A study of Mus musculus with 8 samples.

How the data were processed

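RNA from kidney cells was sequenced in 8 libraries, 4 of Tomato-negative and 4 of Tomato-positive cells. The cells came from p16-tdTomato mice in which chronic kidney disease had been brought about with a diet rich in adenine, per the labels. The name of the genotype joins p16, a cell cycle inhibitor that marks senescent cells and is made from the Cdkn2a gene, with the red fluorescent protein tdTomato. How the reporter was built and how the cells were sorted is not given in the sources used here. The labels name the cell type of every library as proximal tubular epithelial cell, the cell that takes back most of the filtered salt, glucose and protein. Total RNA was taken up with a kit for single cells (Norgen) and made into libraries with a NEBNext Ultra kit, per the labels' protocols.

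The deposited table held raw counts for 25240 gene symbols, including the tdTomato transgene, with no symbol for a gene encoded in mitochondria. The authors aligned the reads with subread, per the file headers, and used the mouse build mm10, edgeR 3.32.1 and limma 3.46.0, per the submitters' processing notes. The counter, the annotation, the treatment of reads with several matches and the strand setting are not given in the sources used here. Reads of antisense or overlapping genes, and of near-identical copies such as Gsdmc2 and Gsdmc3, Ifit3 and Ifit3b or the Cyp4a genes, can therefore not be told apart with certainty. Positions came from GENCODE M21, which uses the same build (GRCm38), where 14040 of the 14284 tested symbols (98.3%) had a single gene.

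Total counts per library ranged from 13474439 to 19886202, so that 1 CPM (counts scaled to the library total) stood for between 13.5 and 19.9 counts. The floor of 3 counts covers counting error only, since reads without molecular identifiers are not independent molecules, while the 95% bounds of log2 differences come from the paired fit and rest on the spread between libraries. Between libraries of the same group the counts differed by far more than sampling noise (chi-square per degree of freedom between 15.5 and 191 over genes with at least 10 counts), so each library was counted as 1 sample. The labels do not say that the libraries came from separate animals, and p-values measure the spread between these samples.

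The groups and the tests, the 39 gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. Genes were kept with edgeR's filterByExpr (a minimum count of 10 in 4 libraries, 15 in all), which left 14284 genes (56.6%). Tomato-positive was compared with Tomato-negative with edgeR 4.0.16 in R 4.3.3: TMM factors, the quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) of log2 differences were the difference over the root of the F statistic. Lists with at least 3 tested genes were compared with all other genes by camera, with its preset correlation of 0.01 between genes, and by limma 3.58.1 with an estimated correlation and with fry, which does not compare a list with other genes. A last test asked whether the difference between Tomato groups itself differed between the 2 prefixes of the titles, CKD523 and CKD627, whose meaning the labels do not give.

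Each of 4 identifiers in the titles (CKD523_2, CKD523_3, CKD627_1 and CKD627_2) was shared by 1 negative and 1 positive library. After removal of the group means, libraries sharing an identifier correlated across genes at 0.46, 0.32, 0.33 and 0.47, all above the limit of 0.1 set for pairing, so the fit with the identifier as a block is given wherever it changes a call or a count. The correlation with the other identifier of the same prefix was of like size (0.34, 0.42, 0.30 and 0.47), and that with the other prefix lay between -0.58 and -0.31, so the pairing in the data was mainly that of the prefix. The fit without the block, fixed in advance, is called the unpaired fit here and gives the main results, and the fit with it is called the paired fit.

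Named genes were 23 genes of senescence, injury and tubule function, chosen whatever their result. To these were added the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 5 CPM and the same sign in all 4 pairs. Predicted genes were skipped. Up to 4 genes with the smallest p per list of cell type markers and per list past the threshold, and up to 3 per direction for the difference between prefixes, completed the rule. Some genes that meet the rule are not reported here. Members of lists that are named beyond this were chosen after their values were seen.

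Alternatives were the paired fit, the prefix as a covariate, each prefix alone, other scaling factors (DESeq2's, upper-quartile, library size only), other filters, DESeq2 1.42.0, limma-voom with and without sample weights, robust dispersions, a limit of 2-fold, and leaving out each library and each pair. Alternatives of the paired fit, among them the removal of a trend on gene length within each library, were added after the data were seen. Simulated data had the libraries' own depths, their means with the differences between pairs kept, and the spread estimated in the paired fit. They thus follow the model of the paired fit, which favors it over the unpaired fit. On these data the unpaired fit recovered 5% of 100 genes changed 2-fold and 49% of 100 changed 4-fold, with 0 false calls among 14284 genes. The paired fit recovered 49% and 87% with 9 false calls, and the test between prefixes recovered 0% and 10%. With no gene changed, 0 genes were called in each of these 3 designs.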

Results

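Gene counts were compared between Tomato-negative and Tomato-positive kidney cells of p16-tdTomato mice with chronic kidney disease, with 4 libraries per group. The series title asks how senescent cells of the diseased kidney differ from their neighbours. Total counts of the Tomato-negative libraries CKD523_2, CKD523_3, CKD627_1 and CKD627_2 were 14045470, 17102054, 16260281 and 14944998. Those of the Tomato-positive libraries with the same identifiers were 13474439, 17682827, 15242105 and 19886202. In each pair fewer genes were detected in the Tomato-positive library: 16054 and 15739 (negative, then positive) for CKD523_2, 16320 and 15684 for CKD523_3, 16948 and 15008 for CKD627_1, and 17043 and 15838 for CKD627_2. The share of counts in the 10 most abundant genes was also lower in each pair, from 9.27, 9.01, 8.15 and 7.67% to 8.45, 7.03, 6.05 and 6.64%. The cause of these differences was not tested. The largest principal component of the libraries (40.9% of the variance) separated the prefixes CKD523 and CKD627 of the titles. The next (22.5%) separated the Tomato groups. Lists of cell type markers differed between the prefixes over both Tomato groups. The median log2 difference of CKD627 minus CKD523 was -1.62 for proximal tubule markers. Of these, 25 of 38 were lower in every CKD627 library than in any CKD523 library. The median was 2.16 for endothelial, 1.98 for principal cell, 1.83 for intercalated cell and 1.42 for loop of Henle markers. Why the prefixes differ was not tested.

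**Figure D1:**
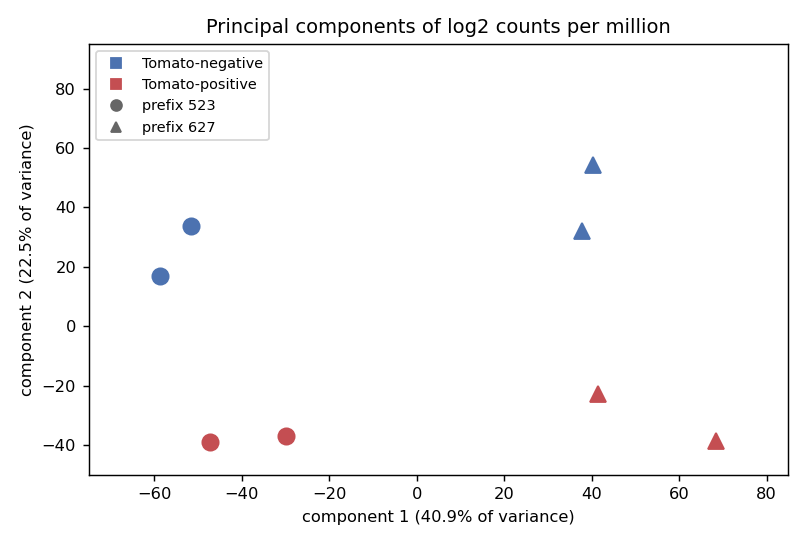
Principal components of log2 CPM in the 8 libraries, with component 1 (40.9% of the variance) on the x axis and component 2 (22.5%) on the y axis. Colours mark the Tomato groups and symbols the prefixes of the titles; the 4 Tomato-positive libraries lie below 0 on component 2 and the 4 Tomato-negative libraries above it.

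tdTomato, the fluorescent reporter that the groups are named for, rose from 111 ± 29.4 CPM (SD, n = 4) in Tomato-negative to 3705 ± 461 CPM (SD, n = 4) in Tomato-positive cells. Its log2 difference was 5.05 ± 0.25 (SE; edgeR adjusted p = 7.08e-05), with 5.37 in prefix CKD523 and 4.80 in prefix CKD627. Cdkn2a, the gene that encodes p16, lay at 1.06 ± 0.949 CPM (SD, n = 4) in Tomato-negative and 1.17 ± 1.11 CPM (SD, n = 4) in Tomato-positive cells. Its log2 difference of 0.14 ± 0.88 (SE) did not pass (edgeR adjusted p = 0.949). The negative libraries CKD523_2, CKD523_3, CKD627_1 and CKD627_2 held 4, 5, 39 and 21 Cdkn2a counts, and their positive partners 14, 6, 8 and 57, so that Cdkn2a was higher in 3 pairs and lower in 1.

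The Cdkn2a locus (mm10, chromosome 4, 89274471 to 89294653, minus strand) makes p16INK4a and p19ARF from overlapping transcripts, which counts per gene do not separate. tdTomato is a transgene with no place in the mm10 build. In the paired fit the Cdkn2a difference was 0.21 on the log2 scale, with 95% bounds of -1.78 and 2.20, against 4.61 and 5.55 for tdTomato. A rise of Cdkn2a as large as that of tdTomato thus lay outside its interval, while a 4-fold rise lay inside it. The estimate was 1.14 in prefix CKD523 and -0.14 in prefix CKD627. Without the negative library CKD523_2, the negative library CKD523_3, the positive library CKD627_2 or the pair CKD523_2 it was -0.17, -0.17, -0.75 and -0.13.

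**Figure D2:**
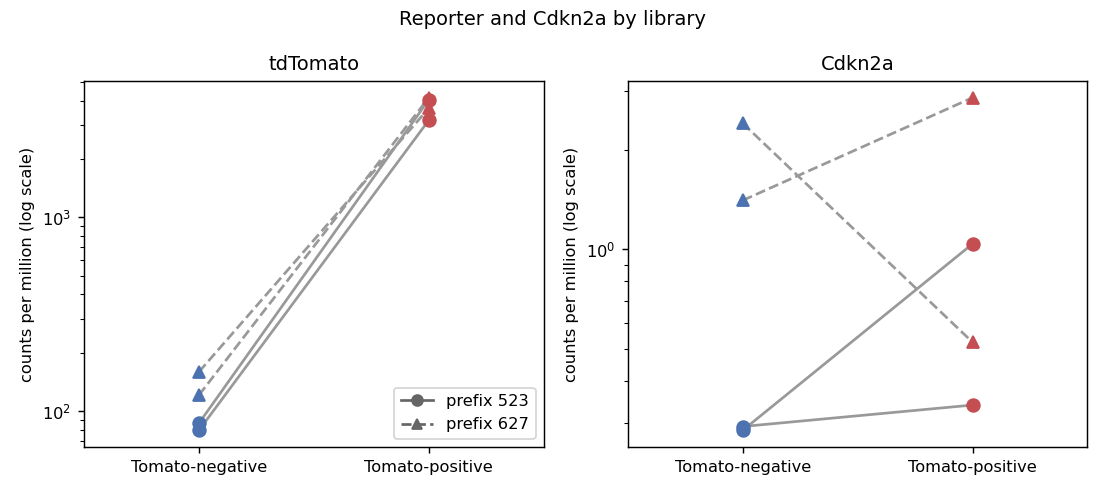
CPM of tdTomato (left) and Cdkn2a (right) in each library on log axes, with lines joining the libraries that share an identifier and symbols marking the prefixes of the titles. tdTomato was at 79.5 to 159 CPM in the 4 Tomato-negative and 3167 to 4143 CPM in the 4 Tomato-positive libraries, while Cdkn2a lay between 0.285 and 2.87 CPM with no common direction. These CPM are scaled to library totals, unlike the group means in the text, which use TMM factors.

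Beside the reporter, Aqp4, the water channel of the basolateral membrane of collecting duct principal cells, rose 10.3-fold in the paired fit, from 31.2 ± 9.84 to 314 ± 57.8 CPM (SD, n = 4 per group). Kap, an androgen-regulated protein of the proximal tubule, was at 4813 ± 2496 CPM in Tomato-negative and 530 ± 257 CPM in Tomato-positive cells (SD, n = 4 per group). Its log2 level fell by 3.18 ± 0.47 (SE; adjusted p = 0.0387). Other genes with large rises were Ptprh, a receptor tyrosine phosphatase (log2 3.39 ± 0.44, adjusted p = 0.0298), and Elf5, a transcription factor of secretory epithelia (2.59 ± 0.26, adjusted p = 0.00935). Lpl, which frees fatty acids from lipoproteins, fell from 355 ± 132 to 93.6 ± 26.7 CPM (log2 -1.92 ± 0.30, adjusted p = 0.041). Other named genes that fell were Acsm3, an acyl-CoA synthetase (-2.86), Mogat1, a monoacylglycerol acyltransferase (-2.85), Cyp4a14, a fatty acid hydroxylase (-2.40), Acot3 (-1.77) and Nudt19 (-1.42) of the peroxisome. Also lower were the ATP synthase genes Atp5k (-1.65) and Atp5g1 (-1.30), and Cox7a2, a subunit of cytochrome c oxidase (-1.10 ± 0.16, adjusted p = 0.0387).

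Among the other named rises were the kinase gene Ros1 (2.81), the interferon-induced Oas2 (2.77), the mucin gene Muc4 (2.58), the ligand gene Wnt9b (2.51), the cilium gene Cfap44 (2.75) and Fcgbp (2.50), a protein of mucus. The pore-forming gasdermin genes Gsdmc3 (3.47, adjusted p = 0.0473) and Gsdmc2 (2.76) rose as well. Reads shared between these close copies make their separate values uncertain. Cwh43 fell by 2.28 and Pm20d1 fell by 1.46 on the log2 scale. All of these 24 genes had the same sign in all 4 pairs, which the rule for naming required. Aqp4 lies on chromosome 18 (15389496 to 15410982, minus strand), Kap on chromosome 6 (133849851 to 133853762, minus strand) and Ptprh on chromosome 7 (4548612 to 4604041, minus strand) of mm10, all protein-coding. Within prefixes CKD523 and CKD627 the log2 differences were 3.24 and 3.42 for Aqp4, -3.50 and -2.64 for Kap, and 2.94 and 3.94 for Ptprh.

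In all, 85 of 14284 genes passed in edgeR, 52 higher and 33 lower in Tomato-positive cells. All had the same sign in both prefixes, which selection by a fit of all 8 libraries makes likely by itself. Over all 14284 genes the log2 differences within the 2 prefixes correlated at 0.36 (Pearson). The paired fit called 1089 genes, 545 higher and 544 lower, among them all 85. Fitted alone, prefix CKD523 gave 2236 and prefix CKD627 gave 287. Without any 1 library 6 to 26 genes passed unpaired, and without any 1 pair 1 to 4. The paired count was 203 without CKD523_3, 384 without CKD627_2 and 521 without CKD523_2. DESeq2 called 1000 genes unpaired and 2026 paired.

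The energy genes of the mitochondrion were lower as a list in Tomato-positive cells (camera adjusted p = 1.18e-40, adjusted p = 0.337 with an estimated correlation). Of 44 tested nuclear genes of oxidative phosphorylation, 9 fell over all genes, 44 fell adjusted over the list alone, and none rose. With the pairing 40 fell over all genes, and the median log2 difference was -0.72 (-0.66 in prefix CKD523, -0.81 in prefix CKD627). Examples were Ndufa4 (-0.86 ± 0.13, adjusted p = 0.0407) and Ndufb10 (-0.86 ± 0.14, adjusted p = 0.0473) of complex I, and Sdhb of succinate dehydrogenase (-0.90 ± 0.15, adjusted p = 0.0473). By fry, which asks only whether the list moved, the adjusted p was 0.0106.

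The lists of fatty acid oxidation and of the tricarboxylic acid cycle were lower as well (camera adjusted p = 2.14e-15 and 1.17e-07, adjusted p = 0.337 with an estimated correlation for both). Of 36 genes of fatty acid oxidation and the peroxisome, 2 fell over all genes, Cyp4a14 and Etfa, which carries electrons from fatty acid oxidation to the respiratory chain (-0.81 ± 0.13, adjusted p = 0.0473). 21 fell adjusted over the list alone and 17 fell over all genes with the pairing. Among these were the dehydrogenase Acadl (-0.66 ± 0.13, paired adjusted p = 0.0199, 0.0603 unpaired) and the trifunctional protein subunit Hadhb (-0.92 ± 0.21, paired adjusted p = 0.0348, 0.0663 unpaired). Cpt1a, which admits fatty acids to the mitochondrion, did not pass (-0.26 ± 0.23, paired adjusted p = 0.529). Of 20 genes of the tricarboxylic acid cycle and gluconeogenesis, 1 fell (Sdhb), 11 adjusted over the list alone and 9 with the pairing. The medians with the pairing were -0.63 (-0.80 and -0.38 in prefixes CKD523 and CKD627) and -0.52 (-0.67 and -0.36).

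The paired counts of these 3 lists depended on single pairs. Without CKD523_3, 1 gene of oxidative phosphorylation, 2 of fatty acid oxidation and none of the tricarboxylic acid cycle fell in edgeR; without CKD627_2 the counts were 7, 10 and 2; and without CKD523_2 they were 19, 7 and 1. Without CKD627_1 they were 40, 27 and 12.

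Markers of the collecting duct principal cell, which takes up water and sodium under hormonal control, were higher as a list in Tomato-positive cells (camera adjusted p = 1.17e-07, lost with an estimated correlation, adjusted p = 0.342 with an estimated correlation). Of 14 tested markers, Aqp4 rose over all genes, 3 rose adjusted over the list alone and 10 rose over all genes with the pairing. Aqp2, the vasopressin-regulated water channel, was at 439 ± 452 CPM in Tomato-negative and 1648 ± 988 CPM in Tomato-positive cells (SD, n = 4 per group; paired log2 2.43 ± 0.34, adjusted p = 0.0062, 0.281 unpaired). The vasopressin receptor gene Avpr2 rose by 2.01 ± 0.32 (paired adjusted p = 0.00973, 0.233 unpaired) and Fxyd4, a regulator of the sodium pump, by 1.85 ± 0.24 (paired adjusted p = 0.00443, 0.123 unpaired). The sodium channel subunit Scnn1a did not pass (-0.12 ± 0.24, paired adjusted p = 0.799). The median with the pairing was 1.09 (1.39 in prefix CKD523, 0.91 in prefix CKD627).

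Markers of the distal tubule, the loop of Henle and intercalated cells were lower as lists by camera (in that order adjusted p = 5.7e-06, 3.48e-05 and 0.0205). These calls were lost with an estimated correlation (adjusted p = 0.337, 0.337 and 0.662 with an estimated correlation). In the distal convoluted and connecting tubule, 7 of 12 markers fell with the pairing. Among them were the thiazide-sensitive cotransporter Slc12a3 (957 ± 219 to 228 ± 125 CPM; paired log2 -2.24 ± 0.33, adjusted p = 0.00781, 0.0603 unpaired) and the calcium-binding Pvalb (-3.93 ± 0.73, paired adjusted p = 0.0163, 0.0992 unpaired). In the loop of Henle and thick ascending limb 9 of 15 fell with the pairing. Among them were Ppp1r1a (-1.92 ± 0.18, paired adjusted p = 0.00121, 0.0631 unpaired), the growth factor gene Egf (-1.38 ± 0.19, paired adjusted p = 0.00595, 0.124 unpaired) and Umod, which encodes uromodulin (6946 ± 4365 to 3091 ± 1968 CPM; -1.17 ± 0.14, paired adjusted p = 0.00324, 0.334 unpaired). Of 14 intercalated cell markers 5 fell with the pairing. Among them was pendrin, Slc26a4, the chloride and bicarbonate exchanger of the base-secreting type (418 ± 274 to 63 ± 47.6 CPM; -2.62 ± 0.27, paired adjusted p = 0.00196, 0.148 unpaired). The exchanger Slc4a1 of the acid-secreting type did not pass (0.45 ± 0.16, paired adjusted p = 0.114). Unpaired, none of these 3 lists had a member past the threshold over all genes in edgeR (6, 5 and 4 at an unadjusted p under 0.05, 5, 2 and 1 by DESeq2, none by limma-voom). Adjusted over the list alone 5, 2 and none fell.

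The medians with the pairing, followed by those in prefixes CKD523 and CKD627, were -1.53 (-1.72 and -0.92) for the distal list, -0.99 (-1.18 and -1.13) for the loop of Henle and -0.64 (-0.62 and -0.95) for intercalated cells. The loop of Henle count was 5 without CKD523_3 or CKD627_2. The intercalated list did not pass without the positive library CKD523_2 (adjusted p = 0.301), the negative library CKD627_1 (0.159) or CKD627_2 (0.141), the pair CKD523_3 (0.0766), or in prefix CKD523 alone (0.0876).

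**Figure D3:**
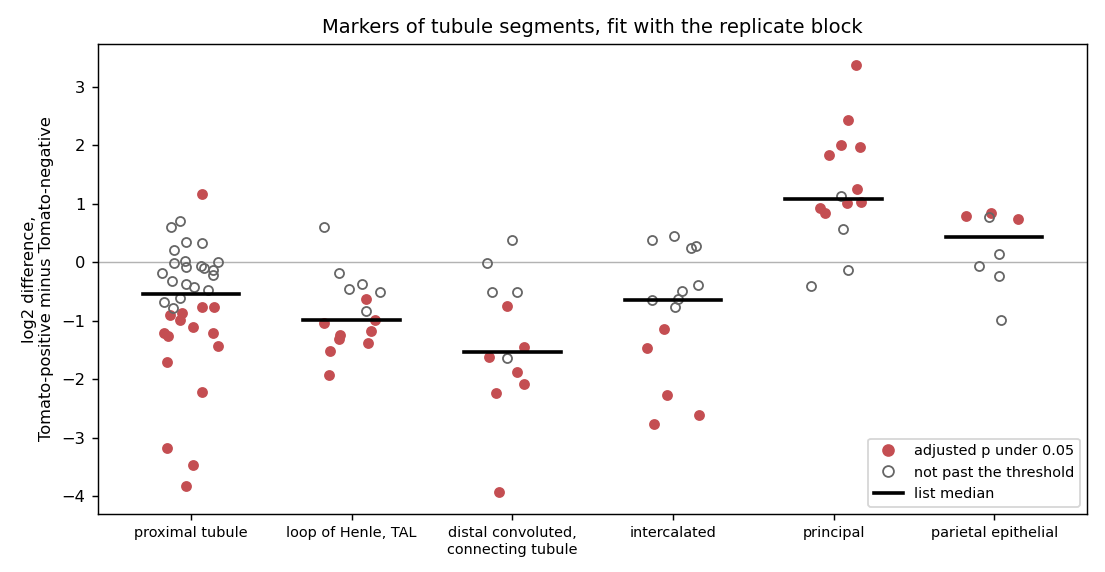
Log2 differences (Tomato-positive minus Tomato-negative, fit with the identifier as a block) of the tested markers of 6 kidney epithelial lists, 1 point per gene, filled where the adjusted p was under 0.05, with a bar at each list's median. Slc22a7 is not drawn because no Tomato-positive library held a count of it; the principal cell median was 1.09, and the medians of the proximal, loop of Henle, distal and intercalated lists were -0.54, -0.99, -1.53 and -0.64.

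The proximal tubule, the cell type the labels name, was split. Of its 38 markers, Kap and Slc22a7 fell over all genes, 6 fell adjusted over the list alone, and with the pairing 16 fell and 1 rose. Slc22a7, an organic anion transporter, had 151 counts over the Tomato-negative and 0 over the Tomato-positive libraries. With 3 counts over the Tomato-positive group as the floor, its pooled level was 53.5-fold lower. This ratio leaves out the spread between libraries and is no lower limit. The amino acid transporter Slc7a13 (121 ± 112 to 9.55 ± 7.58 CPM; paired log2 -3.46 ± 0.23, adjusted p = 5.50e-04, 0.0621 unpaired) and the protease Napsa (-2.21 ± 0.16, paired adjusted p = 5.97e-04, 0.0847 unpaired) fell with the pairing. Cyp7b1, an oxysterol hydroxylase, rose with it (1.16 ± 0.25, paired adjusted p = 0.0261, 0.337 unpaired). The endocytic receptor Lrp2 (-0.08 ± 0.30, paired adjusted p = 0.893), the phosphate transporter Slc34a1 (-0.17 ± 0.18, paired adjusted p = 0.607) and the transcription factor Hnf4a (-0.06 ± 0.28, paired adjusted p = 0.927) did not pass.

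The proximal list's median with the pairing was -0.54, also with Slc22a7 set to its pooled ratio, and was -0.90 in prefix CKD523 and -0.02 in prefix CKD627. Camera gave an adjusted p of 2.21e-06, lost with an estimated correlation (adjusted p = 0.581 with an estimated correlation) and in prefix CKD627 alone (adjusted p = 0.0887). The paired count of 17 was 8 without CKD523_3 and 10 without CKD523_2.

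Among senescence genes, the cyclin-dependent kinase inhibitors other than Cdkn2a did not pass: the paired log2 difference was 0.36 ± 0.21 for Cdkn1a, which encodes p21 (adjusted p = 0.318), 0.77 ± 0.24 for Cdkn2b (adjusted p = 0.0875) and 0.23 ± 0.13 for Cdkn1b. Neither did Trp53 (0.26), the lamin gene Lmnb1 (0.27), the lysosomal galactosidase gene Glb1 (-0.49), the proliferation marker Mki67 (-0.09) or the survival gene Bcl2l1 (0.09). In the list of 17 cell cycle inhibitors and senescence regulators no member passed in edgeR with or without the pairing, over all genes or adjusted over the list alone (1 unpaired and 2 paired at an unadjusted p under 0.05, 1 paired by DESeq2, none by limma-voom). The list did not differ from other genes in camera (median with the pairing 0.17; 0.19 in prefix CKD523, -0.07 in prefix CKD627; camera adjusted p = 0.7). Of 25 targets of p53, Plk2, a stress-induced kinase, rose (1.12 ± 0.14, adjusted p = 0.0241), and 2 rose adjusted over the list alone. With the pairing 3 rose, adding the apoptosis gene Pmaip1 (0.98 ± 0.15, paired adjusted p = 0.00924, 0.075 unpaired) and the stress cytokine gene Gdf15 (0.92 ± 0.18, paired adjusted p = 0.0218, 0.213 unpaired). The p53 list's median was 0.25 (0.18 in prefix CKD523, 0.21 in prefix CKD627). The paired count of 3 was 1 without CKD523_3 or CKD627_2. By camera the adjusted p was 0.0159, lost with an estimated correlation (adjusted p = 0.337 with an estimated correlation), without the negative library CKD627_2 (adjusted p = 0.0656) and in prefix CKD627 alone (adjusted p = 0.115).

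Secreted factors of senescent cells (the senescence-associated secretory phenotype) did not pass as a list of 45 tested genes (camera adjusted p = 0.068; 0.0371 with the pairing, and adjusted p = 0.53 with the pairing and an estimated correlation). No member passed over all genes in edgeR (11 at an unadjusted p under 0.05, 5 by DESeq2, none by limma-voom), and 4 rose and 1 fell adjusted over the list alone. With the pairing 7 rose and 1 fell, with a median of 0.23 (0.56 in prefix CKD523, 0.21 in prefix CKD627). Those that rose with the pairing included the macrophage growth factor gene Csf1 (0.88 ± 0.13, paired adjusted p = 0.00799, 0.0603 unpaired), the cytokine gene Lif (1.18 ± 0.16, paired adjusted p = 0.00525, 0.209 unpaired) and the neutrophil chemokine gene Cxcl1 (0.70 ± 0.16, paired adjusted p = 0.0337, 0.419 unpaired). The urokinase gene Plau fell (-0.82 ± 0.16, paired adjusted p = 0.0182, 0.0631 unpaired). Il6 (1.08 ± 0.65, paired adjusted p = 0.337) and Ccl2 (0.88, 0.131) did not pass. The paired count of 8 was 1 without CKD523_3 or CKD627_2, 4 without CKD523_2 and 13 without CKD627_1.

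The lists of NF-kappaB targets and immediate early genes were higher than other genes by camera with its preset correlation (adjusted p = 0.337 with an estimated correlation for both). Of 38 targets of NF-kappaB, a transcription factor of inflammation, none passed over all genes unpaired in edgeR (20 at an unadjusted p under 0.05, 12 by DESeq2, none by limma-voom), and 14 rose adjusted over the list alone. With the pairing 12 rose and 1 fell, or 21 and 3 adjusted over the list alone. They included the complement gene C3 (692 ± 246 to 1551 ± 412 CPM; 1.21 ± 0.15, paired adjusted p = 0.00337, 0.11 unpaired), the feedback inhibitor gene Tnfaip3 (1.17 ± 0.13, paired adjusted p = 0.00244, 0.091 unpaired) and Nfkbiz (0.90 ± 0.14, paired adjusted p = 0.00902, 0.0819 unpaired). Of 26 immediate early genes, which respond within minutes to signals and to cell dissociation, none passed unpaired in edgeR (15 at an unadjusted p under 0.05, 8 by DESeq2, none by limma-voom), and 11 rose adjusted over the list alone. With the pairing 10 rose (15 adjusted over the list alone), among them Egr1 (0.59 ± 0.12, paired adjusted p = 0.0242, 0.0712 unpaired) and Nr4a1 (0.78 ± 0.15, paired adjusted p = 0.0182, 0.0847 unpaired). The medians with the pairing were 0.52 (0.75 and 0.30 in prefixes CKD523 and CKD627) and 0.51 (0.72 and 0.36). The camera test gave adjusted p of 6.74e-07 and 1.81e-08. Without CKD523_3 the paired counts were 3 and 1, without CKD627_2 they were 4 and 3, without CKD523_2 they were 6 and 4. In prefix CKD627 alone the NF-kappaB list did not pass (adjusted p = 0.16).

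Markers of injured proximal tubule were higher as a list (camera adjusted p = 0.00386, adjusted p = 0.464 with an estimated correlation). Of 36 tested, none passed over all genes unpaired in edgeR (8 at an unadjusted p under 0.05, 5 by DESeq2, none by limma-voom), 5 rose adjusted over the list alone and 7 rose with the pairing. They included the adhesion molecule gene Vcam1 (0.99 ± 0.23, paired adjusted p = 0.0386, 0.0888 unpaired), the developmental transcription factor Sox4 (0.76 ± 0.15, paired adjusted p = 0.0218, 0.079 unpaired) and the keratin gene Krt18 (0.85 ± 0.21, paired adjusted p = 0.0456, 0.105 unpaired). The injury markers Havcr1 (-0.08 ± 0.14, paired adjusted p = 0.761), Lcn2 (0.96 ± 0.26, paired adjusted p = 0.0597) and Spp1 (-0.35 ± 0.17, paired adjusted p = 0.248) did not pass. The median with the pairing was 0.32, with 0.80 in prefix CKD523 and -0.05 in prefix CKD627. The camera call was also lost without CKD523_2 (adjusted p = 0.0963) or CKD523_3 (adjusted p = 0.0642). The paired count of 7 was 1 without CKD523_2 or CKD523_3, 3 without CKD627_2 and 11 without CKD627_1. Vcam1 did not pass without CKD523_2 (adjusted p = 0.123) or CKD523_3 (adjusted p = 0.173).

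Kl, the coreceptor of a phosphate-lowering hormone, was at 425 ± 83.6 CPM in Tomato-negative and 252 ± 31 CPM in Tomato-positive cells (SD, n = 4 per group). It fell with the pairing (-0.74 ± 0.15, paired adjusted p = 0.0218, 0.0852 unpaired). Kl is also a member of the distal convoluted and connecting tubule list, whose median with the pairing was -1.53. Interferon-stimulated genes did not move alike. Of 35 tested, Oas2 rose over all genes (2.77 ± 0.49, adjusted p = 0.0497), and 6 rose and 2 fell adjusted over the list alone. With the pairing 5 rose and 2 fell. Ifit1 rose (0.97 ± 0.24, paired adjusted p = 0.0414, 0.105 unpaired). Ifit3 (-1.29 ± 0.17, paired adjusted p = 0.00514, 0.0631 unpaired) and Ifit3b (-1.38 ± 0.18, paired adjusted p = 0.00514, 0.0618 unpaired) fell. The last 2 are close copies whose separate values are uncertain. The median was 0.31 (0.51 in prefix CKD523, 0.26 in prefix CKD627). The camera test gave adjusted p of 0.00543, lost with an estimated correlation (adjusted p = 0.337 with an estimated correlation) and in prefix CKD627 alone (adjusted p = 0.064). The paired count of 7 was 3 without CKD523_3 or CKD627_2 and 4 without CKD523_2.

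**Figure D4:**
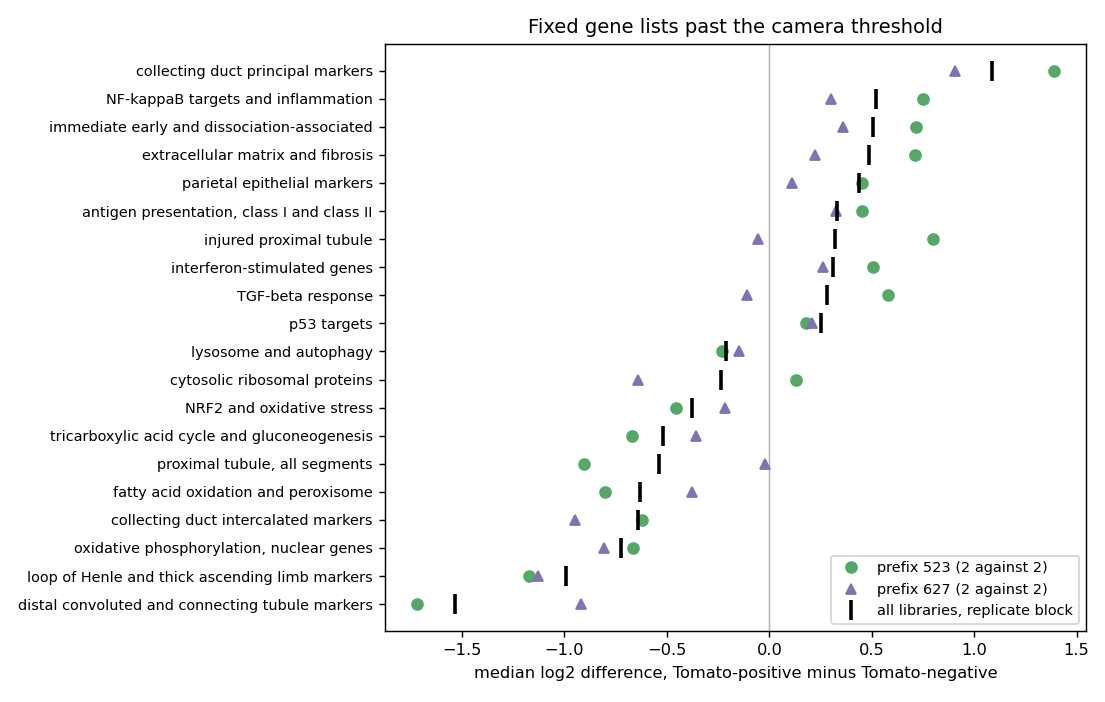
Median log2 difference (Tomato-positive minus Tomato-negative, x axis) of the 20 gene lists past the camera threshold (y axis), as bars for all 8 libraries with the identifier as a block and as points for each prefix of the titles. Collecting duct principal markers lie highest at 1.09 and distal tubule markers lowest at -1.53, and the injured proximal tubule, TGF-beta and ribosomal lists have medians of opposite sign in the prefixes.

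By camera 20 of 35 tested lists passed, 10 higher and 10 lower. The lists not described above are given among the other observations. With an estimated correlation none passed in limma, paired or unpaired (2 at an unadjusted p under 0.05 in each), while fry called 1 unpaired and 6 paired. In prefix CKD627 alone camera called 13. Of the 28 lists with a gene called in the paired fit, the count moved by more than 1.5 times in 24 without CKD523_3, 22 without CKD627_2, 20 without CKD523_2 and 6 without CKD627_1. The counts of the distal, principal and intercalated lists stayed within 1.5 times without any 1 pair. The paired intercalated count of 5 was 9 by DESeq2 and 8 by limma-voom.

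The last comparison asked whether the Tomato difference itself differed between prefixes CKD523 and CKD627. Wnt4, a ligand of tubule formation and repair, was higher in Tomato-positive cells by 2.58 on the log2 scale in prefix CKD523 and by 0.16 in prefix CKD627 (difference -2.42, edgeR adjusted p = 0.0191). Kcnj1, the potassium channel of the thick ascending limb and collecting duct, had a difference of -1.99 in prefix CKD523 and 0.28 in prefix CKD627 (difference 2.28, adjusted p = 0.0191). Wnt4 lies on chromosome 4 (137277489 to 137299726, plus strand) and Kcnj1 on chromosome 9 (32372493 to 32399197, plus strand) of mm10. These 2 genes were the only calls among 14284 in the unpaired fit, and 20 genes passed with the pairing, 13 with a larger difference in prefix CKD627 and 7 with a smaller. Among those 20 were the endocytic receptor genes Lrp2, of the genes chosen in advance (-0.87 in prefix CKD523, 0.68 in prefix CKD627, paired adjusted p = 0.0471, 0.136 unpaired) and Cubn (-0.88 and 0.69, paired adjusted p = 0.0475, 0.234 unpaired), the latter named after its value was seen.

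With 2 libraries per group and prefix this count was unstable. It was 1495 without the negative library CKD627_2 and 0 in edgeR without any 1 of the other libraries except the negative library CKD627_1. In the fit of all 8 libraries 1880 genes had an unadjusted p under 0.05. DESeq2 called 280 genes and limma-voom 5.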

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

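The tests on labels, on Cdkn2a bounds and on the shares of proximal, loop of Henle, distal and intercalated cells were chosen only after the result was seen. The limit for the share of proximal cells in each prefix was first the standard error of the difference, by which CKD627 argued against that share, and was widened to the SD of the proximal genes once the values were known. Tests on gene length, on further principal cell genes and on the difference between prefixes were set before their results were seen.

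In 11 of 302 groups of 4 libraries, for the named genes, 1 library lay far from the other 3 by Dixon's test, where chance gives about 15.1. In Tomato-positive CKD523_2, the lowest of its group, Aqp4 was at 229 CPM (others 337 to 355) and Tmem45b at 137 CPM (others 163 to 164). Tomato-positive CKD627_2 was highest for the neutrophil lipocalin gene Lcn2 at 2722 CPM (others 2024 to 2114) and for Kl at 298 CPM (others 231 to 240), and lowest for the macrophage receptor gene Csf1r at 1.99 CPM (others 11.4 to 16). Tomato-positive CKD627_1 was lowest for Nfkbiz at 420 CPM (others 636 to 651). Tomato-negative CKD627_1 was highest for Bcl2l1 at 228 CPM (others 193 to 199) and for the ribosomal gene Rplp1 at 856 CPM (others 457 to 504). Tomato-negative CKD627_2 was lowest for the glutathione transferase gene Gstp1 at 77.9 CPM (others 116 to 123) and for Slc22a7 at 0.827 CPM (others 2.76 to 3.28). Tomato-negative CKD523_3 was highest for Idh3b, a gene of the tricarboxylic acid cycle, at 298 CPM (others 246 to 252).

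The Tomato difference of Wnt4 was smaller in prefix CKD627 than in prefix CKD523 by a log2 difference of -2.42, and that of Kcnj1 was larger by 2.28, both by the test of the difference itself (edgeR adjusted p = 0.0191).

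tdTomato was higher in every Tomato-positive library while no difference of Cdkn2a, the gene the reporter is named for, was detected. Swapped labels were argued against by tdTomato itself, since the lowest Tomato-positive library was 19.9 times the highest Tomato-negative one. Too few Cdkn2a counts for a rise as large as that of tdTomato were argued against as well, since the upper 95% bound of the paired Cdkn2a log2 difference was 2.20, below the lower bound of 4.61 for tdTomato. A 2-fold rise of Cdkn2a could have been missed, since the same bound of 2.20 lies above 1. A transgene whose transcript does not follow that of Cdkn2a may also account for the gap and was not tested.

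Principal cell markers were higher as a list, while markers of the loop of Henle, the distal tubule and intercalated cells were lower, by camera with its preset correlation (in that order adjusted p = 0.342, 0.337, 0.337 and 0.662 with an estimated correlation). A lower share of proximal cells alone would raise all others alike. The falls of those 3 lists go against that (highest median -0.64 ± 0.36, SE over genes). They are part of the pattern itself, so this is no separate test. A lower proximal share beside other shifts stays open. A larger share of principal cells may account for the rise and stays open. The median of 14 further principal cell genes was 0.32 ± 0.19 (SE over genes), within its error of the 0.5 set in advance. Whether these 14 genes are found in principal cells alone was not tested, so their median cannot decide on the share of principal cells. Of these, 4 rose: Gata2 (1.53 ± 0.23), Tspan1 (1.32 ± 0.16), Wnt7b (0.87 ± 0.16) and Hoxb9 (0.60 ± 0.13). The other 10 did not pass, 3 of them below 0 (Hoxd8 -0.28, Rap1gap -0.29 and Bace2 -0.14). The most abundant marker, Aqp2, was at 439 CPM in Tomato-negative and 1648 CPM in Tomato-positive cells, the labels name a cell type that should lack it, and no gate that would remove principal cells is given in the sources used here. A change of these genes within 1 cell type, which the Tomato groups could also bring, cannot be told apart from a change of share with bulk counts.

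Oxidative phosphorylation genes were lower in Tomato-positive cells (adjusted p = 0.337 with an estimated correlation). These genes are short, with a median length of 1928 bases against 4368 for all tested genes. Removal of a length trend within each library moved the list's median from -0.72 ± 0.03 to -0.55 ± 0.03 (SE over genes). It left 32 of 44 genes lower in place of 40, which argues against length as the whole cause. The SE over genes leaves out the spread between libraries. Before the removal the median was -0.66 in prefix CKD523 and -0.81 in prefix CKD627. A lower share of proximal cells, which are rich in mitochondria, cannot be told apart in either prefix. In CKD627 the proximal median was -0.022 against -0.81 for oxidative phosphorylation, but proximal genes went both ways (SD 1.65 over 38 genes). There Lrp2 (0.68), Hnf4a (0.55) and Slc34a1 (0.25) lay above 0, while Slc7a13 (-2.97), Kap (-2.64) and Napsa (-1.92) lay below. With a limit as wide as that SD, the comparison could hardly have argued against a lower share. In CKD523 the medians were -0.90 (proximal) and -0.66 (oxidative phosphorylation). A lower share of loop of Henle, distal and intercalated cells stays open in both prefixes, since the highest of their medians was -0.62, and a lower level within the cells of the Tomato-positive group, which the design names, may also underlie the pattern.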

How the results depend on the processing

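The alternatives of the paired fit were chosen after seeing the data, and all others before. The 85 genes called unpaired became 1089 with the replicate block, 2026 with the block in DESeq2, 1527 with the prefix as a covariate, 2236 in prefix CKD523 alone, 287 in prefix CKD627 alone, 45 with no filter, 1000 with DESeq2, 549 with sample weights in limma-voom, 56 at 2-fold and 1 to 26 without 1 library or pair; with other scaling factors, the stricter filter, limma-voom and robust dispersions they stayed between 62 and 110. The paired count of 1089 became 2026 with DESeq2, 464 at 2-fold and 203 to 1319 without 1 pair, and 872 of its calls were among the 1155 after removal of the length trend. The 20 lists became 13 in prefix CKD627 alone, 0 with an estimated correlation, paired or not, 1 with fry and 16 to 21 without 1 library or pair, and 22 with the block. The 2 genes differing between prefixes became 20 with the block, 280 with DESeq2, 5 with limma-voom and 0 to 1495 without 1 library, where the lone library of a group and prefix was assumed to vary like the others. Cdkn2a passed under no alternative that tested it; its log2 difference was -0.14 in prefix CKD627 alone and -0.75 to 1.09 without 1 library or pair, with -0.17 without the negative CKD523_2 or CKD523_3 and -0.13 without the pair CKD523_2, and it was filtered out by the stricter filter and without the pair CKD627_2. Among lists, the ribosomal median turned to 0.13 in prefix CKD523 alone and -0.45 to 0.013 without 1 library or pair (0.013 without the pair CKD627_1), and those of injured proximal tubule and the TGF-beta response to -0.054 and -0.11 in prefix CKD627 alone. Of 6806 further values for named genes and lists, 5782 stayed on their side of the threshold, 437 passed it newly, 583 lost it and 4 that had passed changed direction. The 5782 include 105 values that changed sign while past the threshold in neither setting, which were not counted as reversed. The block changed no call of a list other than the secretory factors and complement. The cause was not tested, beyond that fewer libraries or genes enter some fits. Scaling moved the median of all genes by no more than 0.04. Depth limits most the genes near the floor of 3 counts. Cdkn2a came near it in some libraries, such as the negative CKD523_2 with 4 counts. Its pairs of prefix CKD627 moved in opposite directions, from 39 to 8 and from 21 to 57 counts. The spread between libraries thus also limits its estimate.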

Other observations

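The gene list tests and the tests on the splits of the samples were set before their results were seen, and the comparison of proximal tubule segments was chosen only after the result was seen.

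The lists of NRF2 and oxidative stress, lysosome and autophagy, and cytosolic ribosomal proteins were lower than other genes by camera with its preset correlation (in that order adjusted p = 0.453, 0.453 and 0.711 with an estimated correlation). Of 30 tested genes of NRF2 and oxidative stress, with the pairing 4 fell (14 adjusted over the list alone), among them the peroxidase gene Prdx1 (log2 -0.63 ± 0.15, adjusted p = 0.0413, 0.122 unpaired) and the superoxide dismutase gene Sod1 (-0.57 ± 0.14, adjusted p = 0.0439, 0.201 unpaired). None passed unpaired in edgeR, over all genes or adjusted over the list alone (10 at an unadjusted p under 0.05, 1 by DESeq2, none by limma-voom). The median was -0.38 (-0.45 in prefix CKD523, -0.22 in prefix CKD627; camera adjusted p = 2.08e-04, adjusted p = 0.453 with an estimated correlation). Of 33 lysosome and autophagy genes 2 fell with the pairing, among them Cd63 of lysosomal membranes (-0.62 ± 0.15, adjusted p = 0.0405, 0.204 unpaired), and none passed unpaired in edgeR, over all genes or adjusted over the list alone (7 at an unadjusted p under 0.05, 1 by DESeq2, none by limma-voom). The median was -0.21 (-0.23 and -0.15 in the prefixes; camera adjusted p = 0.0239, adjusted p = 0.453 with an estimated correlation). No gene of 49 cytosolic ribosomal proteins passed in edgeR in either fit (3 unpaired and 5 paired at an unadjusted p under 0.05, 2 paired by DESeq2, 1 paired by limma-voom), and the median was -0.23, with 0.13 in prefix CKD523 and -0.64 in prefix CKD627 (camera adjusted p = 0.0159, adjusted p = 0.711 with an estimated correlation). The lysosome list did not pass camera without the negative CKD523_3 (adjusted p = 0.127), the positive CKD627_1 (0.111), the pair CKD523_3 (0.0666) or CKD627_1 (0.0721), or in prefix CKD523 alone (0.0649). The ribosomal list did not pass without the negative (0.71) or positive CKD627_1 (0.099) or the positive CKD627_2 (0.0578). Its genes are short, with a median length of 1840 bases against 4368 for all tested genes. Removal of the length trend within each library moved its paired median from -0.23 to -0.05, so a lower level apart from length was hardly seen. The paired NRF2 count of 4 was 1 without CKD627_2, and none passed in edgeR without CKD523_2 or CKD523_3.

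Matrix, TGF-beta, parietal epithelial and antigen presentation lists were higher by camera with its preset correlation (in that order adjusted p = 0.581, 0.584, 0.337 and 0.337 with an estimated correlation). Of 34 matrix genes, with the pairing the fibrillin gene Fbn1 (1.05 ± 0.17, adjusted p = 0.00973, 0.12 unpaired) and the collagen gene Col15a1 (1.02 ± 0.18, adjusted p = 0.0138, 0.203 unpaired) rose and Nid2 of basement membranes fell (-1.21 ± 0.20, adjusted p = 0.0102, 0.0861 unpaired). Adjusted over the list alone 12 rose and 2 fell with the pairing, and none passed unpaired in edgeR (10 at an unadjusted p under 0.05, 3 by DESeq2, none by limma-voom). The median was 0.49 (0.71 and 0.22 in prefixes CKD523 and CKD627; camera adjusted p = 0.0114, adjusted p = 0.581 with an estimated correlation). Of 27 genes of the TGF-beta response 5 rose with the pairing, among them the receptor gene Tgfbr2 (0.90 ± 0.18, adjusted p = 0.0212, 0.0618 unpaired) and the inhibitor Smad7 (0.61 ± 0.14, adjusted p = 0.034, 0.1 unpaired). Unpaired none passed in edgeR over all genes (5 at an unadjusted p under 0.05, 2 by DESeq2, none by limma-voom) and 2 rose adjusted over the list alone. The median was 0.28 (0.58 and -0.11; camera adjusted p = 0.0392, adjusted p = 0.584 with an estimated correlation). Of 8 markers of parietal epithelium, the developmental regulator Pax2 (0.79 ± 0.13, adjusted p = 0.0108, 0.0603 unpaired), Ncam1 (0.74) and the claudin gene Cldn1 (0.85) rose with the pairing, and 3 rose unpaired adjusted over the list alone (median 0.44; 0.45 and 0.11; camera adjusted p = 0.0239, adjusted p = 0.337 with an estimated correlation). Of 17 antigen presentation genes 1 rose with the pairing and 5 with the pairing adjusted over the list alone. That 1 gene no longer passed in edgeR with DESeq2's scaling factors, with robust dispersions, at 2-fold, or without CKD523_2, CKD523_3 or CKD627_2, while DESeq2 called 4 and limma-voom 1. Unpaired none passed in edgeR (2 at an unadjusted p under 0.05, 1 by DESeq2, none by limma-voom; median 0.33; 0.45 and 0.33; camera adjusted p = 0.00611, adjusted p = 0.337 with an estimated correlation). The matrix list did not pass camera without the negative CKD523_2 (adjusted p = 0.0794) or CKD523_3 (0.127), the pair CKD523_2 (0.0963) or in prefix CKD627 alone (0.252). The parietal list did not pass without the positive CKD523_2 (0.107) or CKD523_3 (0.0839), the negative CKD627_2 (0.0656), the pair CKD523_2 (0.108) or in prefix CKD627 alone (0.252). The TGF-beta list had adjusted p between 0.0515 and 0.269 without the negative or positive CKD523_2, the negative or positive CKD523_3, the positive CKD627_2, or the pair CKD523_2 or CKD523_3, and 2 of its genes rose without CKD523_2 and none in edgeR without CKD523_3 or CKD627_2. The paired matrix count of 3 was 6 without CKD627_1, 13 by DESeq2 and 7 by limma-voom. Without CKD523_3 no matrix or parietal gene passed in edgeR.

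For the lists that did not pass camera in the unpaired fit, medians and counts are those of the paired fit. Complement and coagulation, with 20 genes, had a median of 0.20 and 2 genes that rose with the pairing (camera adjusted p = 0.18; 0.0357 with the pairing, and adjusted p = 0.371 with the pairing and an estimated correlation). Glycolysis and hypoxia had a median of -0.12 over 30 genes, with 2 higher and 4 lower (camera adjusted p = 0.109); the BCL2 family 0.08 over 14, with 3 higher (0.47); proliferation -0.02 over 34, or 0.02 with library sizes only, with none past the threshold in edgeR, DESeq2 or limma-voom (2 at an unadjusted p under 0.05; 0.7); and the unfolded protein response -0.02 over 28, or 0.02 with library sizes only, with 3 higher and 1 lower (0.7). Purine metabolism had -0.20 over 23, with 2 higher and 2 lower (0.635), and calcium, phosphate and vitamin D 0.18 over 13, with 1 higher and 3 lower (0.625). Among other cell types, fibroblast and mural markers had 0.48 over 17 and endothelial markers 0.16 over 20, with none past the threshold in edgeR (5 and 1 at an unadjusted p under 0.05, 3 and none by DESeq2, none and 1 by limma-voom; camera adjusted p = 0.111 and 0.635), and podocyte markers -0.08 over 12, with 1 lower (0.635). Of 19 macrophage markers 1 rose with the pairing, Cd68 (1.40 ± 0.25, adjusted p = 0.0153, 0.0663 unpaired), and 1 fell (median -0.11, camera adjusted p = 0.665). Dendritic cell markers had 0.78 over 4 (0.478) and erythrocyte markers 0.45 over 3 (0.625). The neutrophil, T and NK cell and B cell lists had 2 tested genes each and were not tested (medians 0.20, -0.31 and 0.94), and the mitochondrially encoded list had 0. Outside the lists, Aldh1a3, which makes retinoic acid (3.07 ± 0.32, paired adjusted p = 0.00201, 0.0995 unpaired) and the neutrophil growth factor gene Csf3 (1.68 ± 0.30, paired adjusted p = 0.0144, 0.162 unpaired) rose with the pairing, named after their values were seen.

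Within the proximal tubule a hypothesis is that genes of its last segment, S3, fell more than those of S1 and S2. The median paired log2 difference was -2.21 over 9 S3 genes, also with Slc22a7 set to its pooled ratio, and 0.01 over 11 genes of S1 and S2, a difference of -2.23. These genes prompted the hypothesis, so no test on them can bear on it and it stays open; a permutation test of them, first counted in its favor, was set aside once its result was known. Cyp7b1 of the S3 set rose, while Slc22a6 (-1.70 ± 0.22, paired adjusted p = 0.00473, 0.164 unpaired) of the S1 and S2 set fell. A smaller share of S3 cells among Tomato-positive cells may account for the difference, as may lower levels within them, and bulk counts do not separate these.

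Of the 35 splits of the 8 libraries into 4 and 4, 2 gave as many genes as the 85 of the real split: the real split and the split by prefix, which gave 1817 and so points to a structure of the samples, while each of the other 33 gave 0 in edgeR. A share of 2 in 35 is above 0.05, so chance is not excluded by this count, and the paired fit, which takes up the prefix, gave 1089. Of those 35 splits 2 gave as many lists as the 20 of the real one, the highest other split giving 22, the split by prefix 18 and the median of the others 12, so chance is not excluded for the count of lists. Of the 8 splits that part all 4 pairs, 1 gave as many genes in the paired fit, the real one with 1089, and the highest other gave 0; 8 splits are too few for a share under 0.05.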
